A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

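The series holds 2 samples of budding yeast chromatin, 1 library each, from strain yFR212. This strain has the W303 laboratory background, and its HTZ1 gene, which encodes the histone variant H2A.Z, carries 3 copies of the Myc epitope at its end. Per the labels' protocols, cells were grown to an optical density of 0.8, fixed with 1% formaldehyde and digested with micrococcal nuclease (MNase), an enzyme that cuts the linker DNA between nucleosomes, for 20 minutes at 37 °C. One library holds DNA of total mononucleosomes. The other holds DNA of mononucleosomes precipitated with an anti-Myc antibody. The labels name the antibody clone differently in different places and give more than one fixation time, so neither is stated here. The samples were grouped by their titles.

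Each library has 2 lists of predicted nucleosome positions on chromosome III, made by the authors separately for the library, 1 from paired-end and 1 from single-end data per the file names. PING, a mixture model of forward and reverse read positions, is named in the series title. BWA, SAMtools and the genome build sacCer2 are named in the submitters' processing notes. Versions, read filters and model settings are not given in the sources used here. The centre, the distance between the forward and reverse read peaks, the variances of the read positions and the standard errors are deposited in bp or squared bp, per the file headers. The deposited mixing weight is a fraction from 0 to 1. The score of each position is the authors' own, with no stated scale, and in all 4 lists the deposited rank follows the score. Scores were therefore used only to describe, rank or filter positions within 1 list, and between lists only the ranks of matched positions were compared. The lists carry no read counts, so the depth of the libraries is unknown, and no floor or interval on reads can be given.

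Positions were compared in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. A position was called matched when the nearest centre of the other list lay within 20 bp. Shares carry 95% Wilson intervals, or exact Clopper-Pearson intervals for windows, chromosome ends and gaps. These intervals treat positions as independent and cover counting error only. The chance level of matching was taken from 10000 circular shifts of the target list along the chromosome, which keep the spacing of both lists. A small part of such shifts nearly restores the original register, so the highest shifted values overstate chance. With 1 library per group no difference between H2A.Z and total chromatin has a replicate check, and no p-value is given. Medians carry order-statistic 95% intervals over positions, which are not replicates.

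The positions named by coordinate follow a rule fixed before the data were examined, along with the match distance, the windows of 10 kb, the ends of 20 kb and the gap minimum of 300 bp. It takes the 5 highest-scoring positions and the 5 longest gaps of each paired-end list, and the 3 windows with the highest and the 3 with the lowest H2A.Z share. Results on the top 10% of a list by score were added after seeing the data. Alternatives covered the match distance, score filters, removal of positions within 100 bp of a higher-scoring one, one-to-one matching, other windows and ends, and single-end in place of paired-end lists. Matching and neighbour-distance statistics were tested on simulated data built from the 2353 total paired-end positions. Planted matched shares from 20 to 80% were recovered with an error of at most 0.416 percentage points. This holds for means over simulations, after correction for the chance level. The matched shares in the results are not corrected in this way and include matches by chance, so this error does not apply to them. Scores planted beside wide distances between centres were found in 40 of 40 simulations, and random scores in 0 of 40. Only a single, large planted increase was run. The random scores were independent between positions, whereas the real top scores were uneven along the chromosome. These counts therefore do not give an error rate for the data.

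Coordinates are those of the lists, in sacCer2. The gene table used here belongs to assembly R64, so positions were not assigned to genes, and the planned comparisons at gene starts and over gene lists were not run. A genome sequence was not used here.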

Results

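Nucleosome positions on chromosome III of budding yeast were mapped in total mononucleosomes and in mononucleosomes enriched for H2A.Z, a histone variant that replaces H2A in a subset of nucleosomes. The total library had 2353 positions from paired-end data and 1881 from single-end data. The H2A.Z library had 2264 and 1859. The positions ran from 171 to 316188 bp, and the paired-end lists held 7.45 positions per kb in total chromatin and 7.16 in the H2A.Z library. There was 1 library per group, so differences between them have no replicate error, and the lists give no read counts or depth.

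The first comparison asked how nucleosomes were spaced in each map. In all 4 lists the most frequent distance between neighbouring centres fell between 160 and 170 bp. This bin held 20.7% of distances in the total single-end list and 16.5% in the H2A.Z single-end list, against 11.3% and 11.4% in the paired-end lists. The median distance in the single-end lists was 162 bp in total chromatin (interquartile range 140 to 175 bp) and 161 bp in the H2A.Z library (136 to 178 bp). Distances of 140 to 200 bp made up 64.3% of the total single-end list (95% interval 62.1 to 66.4%) and 58.1% of the H2A.Z single-end list (55.9 to 60.4%). The paired-end maps held many centres too close for separate nucleosomes on 1 DNA molecule. Neighbours less than 100 bp apart made up 30.6% of distances in the total paired-end list (28.7 to 32.5%) and 26.9% in the H2A.Z paired-end list (25.1 to 28.8%), against 9.04% and 9.80% in the single-end lists. The median distances of the paired-end lists were 136 and 138 bp. Once positions within 100 bp of a higher-scoring one were removed, 1780 total and 1765 H2A.Z paired-end positions remained, with medians of 164 bp in both maps.

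**Figure D1:**
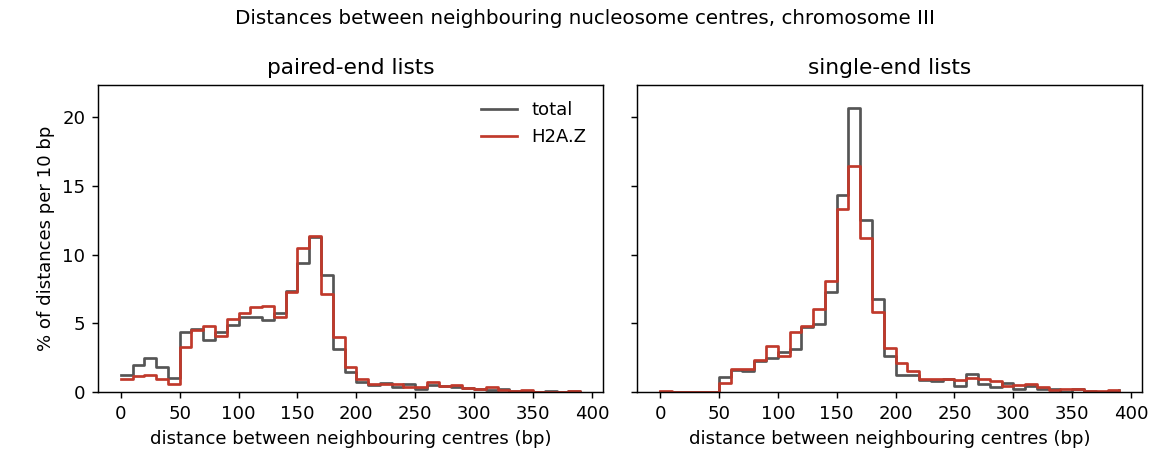
Distances between neighbouring nucleosome centres (x axis, bp) as a percentage of all distances per 10 bp bin (y axis) for the total (grey) and H2A.Z (red) libraries, in paired-end (left) and single-end (right) lists. All 4 curves peak between 160 and 170 bp, and the paired-end lists hold 26.9 to 30.6% of distances under 100 bp.

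The second comparison set positions from single-end data against positions from paired-end data of the same library, the methodological question of the series. In total chromatin 1539 of 1881 single-end positions, or 81.8% (80.0 to 83.5%), had a paired-end position within 20 bp, against a mean of 28.7% over circular shifts. In the H2A.Z library the share was 1507 of 1859, or 81.1% (79.2 to 82.8%), against 28.0%. No shift of 10000 reached either observed share. In the reverse direction 66.7% of total (64.8 to 68.6%) and 67.0% of H2A.Z paired-end positions (65.0 to 68.9%) had a single-end partner. Matched centres lay a median of 3.71 bp apart in total chromatin and 3.32 bp in the H2A.Z library, with median signed offsets of 0.0847 and 0.0972 bp. Positions also ranked alike by score. Spearman's rho over mutually nearest positions was 0.913 in total chromatin (1539 positions) and 0.953 in the H2A.Z library (1506 positions), positions not being independent replicates.

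The distance between read peaks and the fuzziness of positions differed more between list types than between libraries. The median distance between forward and reverse read peaks was 126 bp in the total paired-end list (interquartile range 122 to 131 bp) and 125 bp in the H2A.Z paired-end list (121 to 129 bp), and 128 bp in both single-end lists. The SD of forward read positions around a centre, a measure of how fuzzy a position is, had a median of 25.4 bp in the total and 26.8 bp in the H2A.Z paired-end list, against 30.0 and 30.8 bp in the single-end lists. The median standard error of the centre was 1.75 bp in total chromatin and 2.44 bp in the H2A.Z library for paired-end data. For single-end data it was 2.23 and 2.78 bp. The interquartile ranges of the libraries overlapped for each parameter. Of the paired-end positions, 61 total and 23 H2A.Z entries had a reverse-strand variance above 10000 squared bp, and 0 had such a forward variance, so the forward SD is used here.

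**Figure D2:**
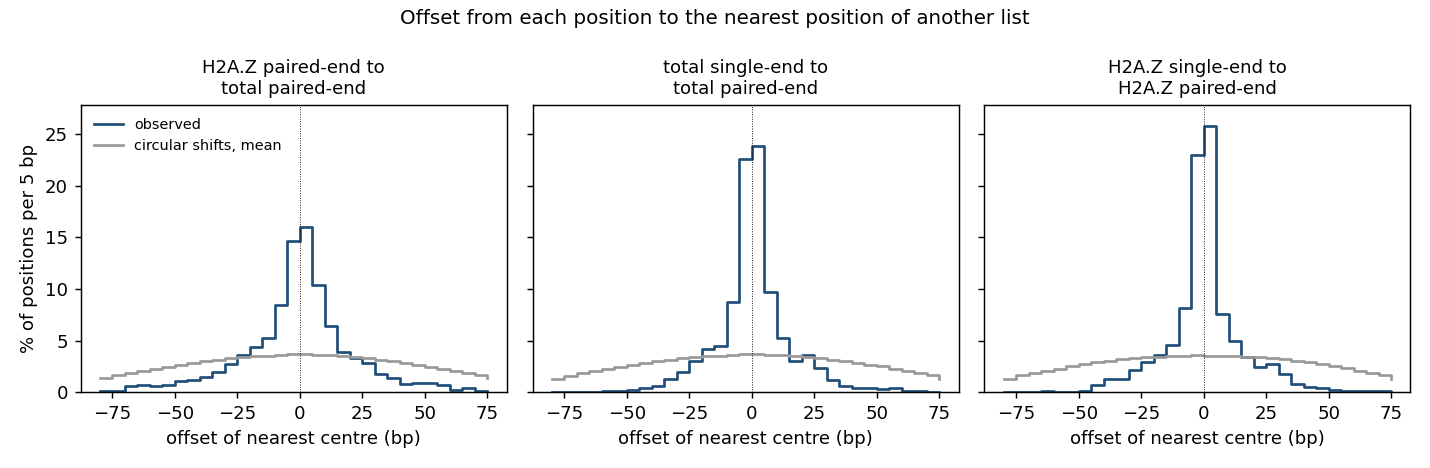
Distance from each position to the nearest position of another list (x axis, bp) as a percentage of positions per 5 bp bin (y axis), observed (blue) and as the mean of 1000 circular shifts (grey). The 3 panels compare H2A.Z with total paired-end positions, and single-end with paired-end positions in each library, and all peak at an offset near 0 bp.

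The central comparison asked which nucleosomes of total chromatin were found in the H2A.Z library. The H2A.Z library gave positions mostly at the places found in total chromatin. It held nearly as many paired-end positions, 2264 against 2353, and background carried through the precipitation was not measured. An H2A.Z position here means a position in that library's list, and need not be a nucleosome that carries H2A.Z. Of 2264 H2A.Z paired-end positions, 1572 lay within 20 bp of a total position, or 69.4% (67.5 to 71.3%), against 28.7% over circular shifts. Within 73 bp, about the distance from the centre of a nucleosome to its edge, the share was 97.2% (96.5 to 97.8%), against 85.1% by chance, leaving 63 H2A.Z positions without a total partner. Conversely, 67.9% of total positions (66.0 to 69.7%) had an H2A.Z position within 20 bp, and 66 had none within 73 bp. Matched centres lay a median of 5.84 bp apart, with a median signed offset of 0.440 bp, total minus H2A.Z. In the single-end lists 82.4% of H2A.Z positions (80.6 to 84.0%) had a total position within 20 bp, against 23.8% by chance.

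Score ranks at these positions were less alike between libraries than between list types of 1 library. List types of 1 library share the same DNA sample, so they are no baseline for separate libraries. How alike the ranks of separate total libraries would be is unknown. Spearman's rho between H2A.Z and total scores was 0.575 over 1555 mutually nearest paired-end positions (bootstrap interval over positions 0.536 to 0.610). In single-end lists it was higher, 0.643 over 1531 positions (0.609 to 0.675). Of the 226 H2A.Z positions in the top 10%, 95.1% (91.5 to 97.3%) lay within 20 bp of a total position, against 66.6% (64.5 to 68.6%) of the other 2038. The same contrast held for total positions against the H2A.Z list. Of their top 10% 97.9% (95.1 to 99.1%) were matched, against 64.5% (62.5 to 66.6%) of the others. A total position that was itself in the top 10% lay within 20 bp of 100 of the 226, or 44.2% (37.9 to 50.8%). Unrelated ranks would give 9.50% if strong and weak total positions were matched equally often. Strong ones were matched more often, so this baseline is too low. The strong H2A.Z positions had a median forward SD of 21.1 bp, against 27.3 bp for the other H2A.Z positions. In total chromatin the medians were 21.0 and 25.9 bp.

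The highest-scoring H2A.Z position had its centre at 289253 on chromosome III, with a score of 19.7 and a standard error of 0.883 bp. The nearest total position, 5.71 bp away at 289258, ranked 42 of 2353. The second, at 52671, scored 15.7, and its total partner 5.37 bp away ranked 122. The third, at 46896, scored 14.1, and its total partner 1.71 bp away ranked 5. The fourth, at 185989, scored 13.7, with a total partner 6.72 bp away that ranked 10. The fifth, at 246584, scored 13.5, while its total partner 5.36 bp away ranked only 570. In the single-end H2A.Z list these centres were found within 5.36 bp and ranked 5, 7, 2, 1 and 10. Each of the 5 had exactly 1 other top 10% H2A.Z position 220 to 400 bp away. For the first this was the position at 289540, with a score of 5.97, and neither total list had a centre between them more than 50 bp from both. For the second and the fifth, both total lists had 1 such centre between the position and its partner. For the third only the single-end list had 1, and for the fourth only the paired-end list.

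The 5 highest-scoring total positions had centres at 213811, 136485, 106635, 207246 and 46898, with scores of 4.98, 4.58, 4.42, 4.42 and 4.35. Their nearest H2A.Z positions lay 0.127 to 9.25 bp away and ranked 50, 348, 316, 271 and 3 of 2264. The position near 46898 was the only one among the first 5 of both lists.

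**Figure D3:**
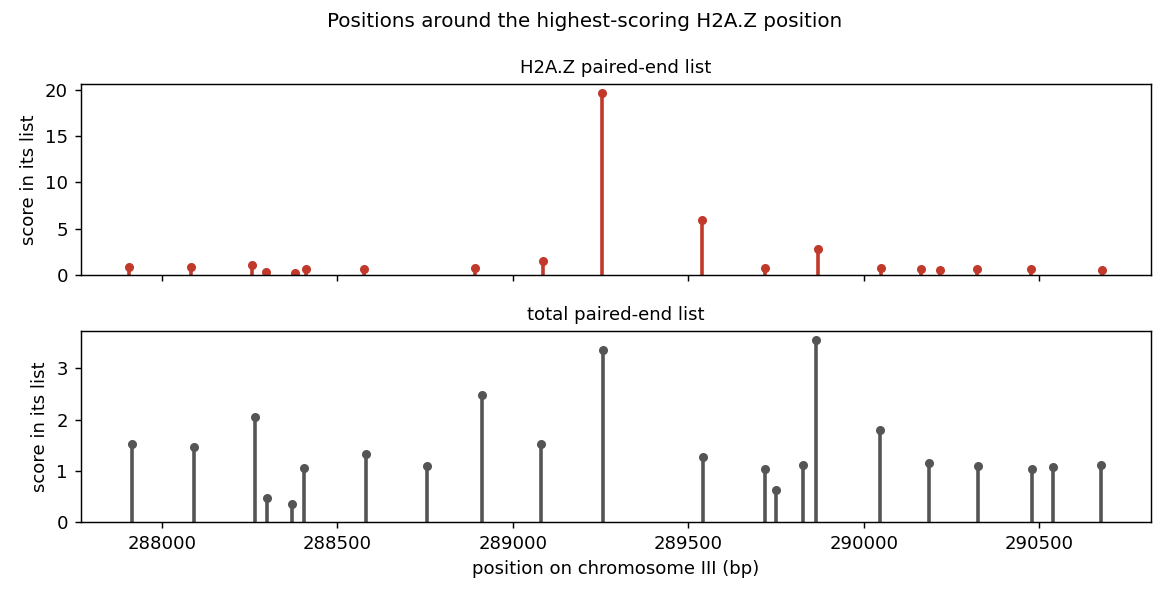
Paired-end positions from 287753 to 290753 on chromosome III (x axis, bp), each drawn as a line whose height is its score within its own list (y axis), for the H2A.Z (top) and total (bottom) libraries on separate scales. The H2A.Z position at 289253 scored 19.7 and the next highest, at 289540, scored 5.97, while the 22 total positions scored between 0.360 and 3.56.

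The last comparison asked whether H2A.Z positions were spread along the chromosome like total positions. By number the comparison had little room to show a difference, since 97.2% of H2A.Z positions lay within 73 bp of a total position. H2A.Z positions made up 49.0% of all paired-end positions, and the exact 95% interval included this value in each of the 32 windows of 10 kb. The highest shares were 53.5% from 90 to 100 kb (45.4 to 61.5%), 52.4% from 0 to 10 kb (44.6 to 60.1%) and 52.1% from 10 to 20 kb (42.7 to 61.5%). The lowest were 45.3% from 180 to 190 kb (38.1 to 52.6%), 45.6% from 30 to 40 kb (37.4 to 54.0%) and 46.2% from 210 to 220 kb (37.9 to 54.7%). The share was 49.6% in both 20 kb ends together (45.5 to 53.7%) and 49.0% in the rest (47.4 to 50.5%).

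By score both libraries were uneven along the chromosome. Windows held between 0 and 17 of the 226 top 10% H2A.Z positions, and the variance over windows was larger than in 10000 of 10000 random assignments of the top scores to H2A.Z positions. The same held for the top 10% of total positions, with a variance of 21.0 against 16.1 in H2A.Z. For H2A.Z the window from 70 to 80 kb was richest, with 17 of 68 positions in the top 10% (exact interval 15.3 to 37.0%). This window was also rich in total chromatin, with 16 of 75 positions, or 21.3% (12.7 to 32.3%). The windows from 0 to 10 kb and from 80 to 90 kb had 0 of 89 and 0 of 42 for H2A.Z, which exact intervals limit to 4.06% and 8.41%. Total chromatin had few there as well, 4 of 81 (1.36 to 12.2%) and 2 of 43 (0.568 to 15.8%). In the first 20 kb only 2 of 150 H2A.Z positions were in the top 10%, or 1.33% (0.162 to 4.73%), against 10.7% (9.35 to 12.1%) in the chromosome between the ends. The last 20 kb had 14 of 148, or 9.46% (5.27 to 15.4%). The top 10% of total positions made up 5.11% of those in the first 20 kb (2.08 to 10.2%), 2.41% in the last 20 kb (0.660 to 6.05%) and 10.9% between the ends (9.61 to 12.4%).

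**Figure D4:**
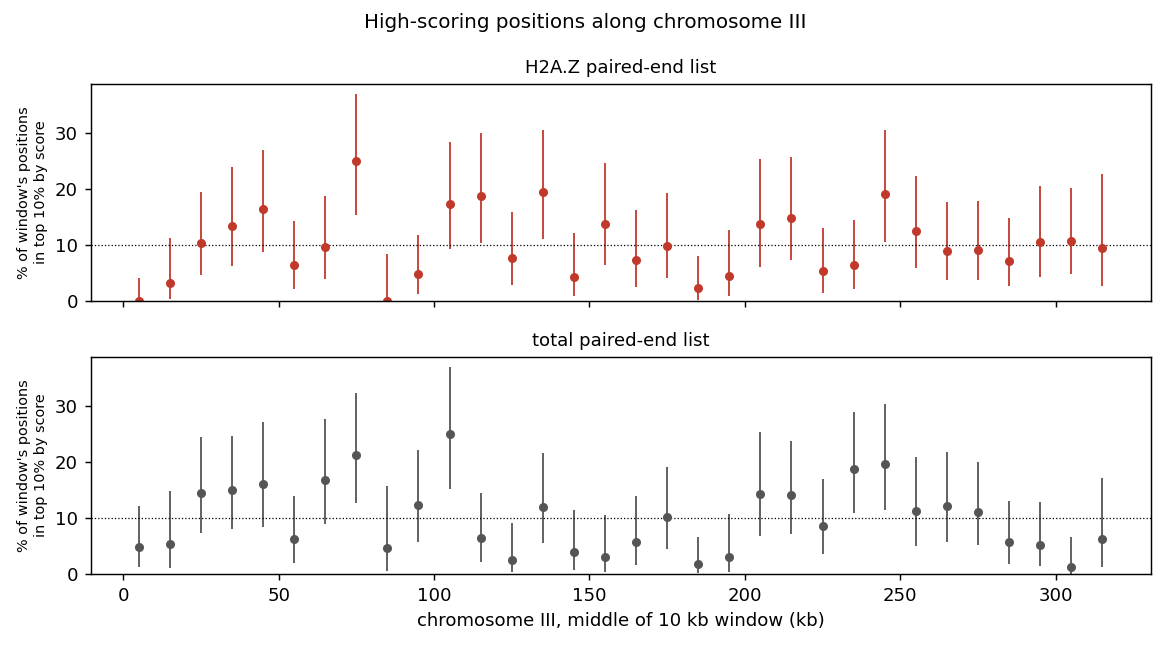
Percentage of a window's paired-end positions that belong to the top 10% of their list by score (y axis) in windows of 10 kb along chromosome III (x axis, kb), for H2A.Z (top) and total (bottom), with exact 95% intervals for counting error and a dotted line at 10%. The H2A.Z values run from 0% in the windows from 0 to 10 kb and 80 to 90 kb to 17 of 68 positions from 70 to 80 kb.

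Stretches without positions were found at the same places in both libraries where they were long. The total paired-end list had 37 gaps of more than 300 bp between neighbouring centres and the H2A.Z list had 38. Of the total gaps 16 held an H2A.Z position more than 20 bp from either edge, or 43.2% (27.1 to 60.5%), and of the H2A.Z gaps 18 held a total position, or 47.4% (31.0 to 64.2%). The 5 longest gaps of the total list ran from 148545 to 151864, 88126 to 90720, 12244 to 14032, 199481 to 201150 and 85153 to 86742, with lengths of 3319, 2594, 1788, 1669 and 1589 bp. The 5 longest gaps of the H2A.Z list were at these same places, from 148543 to 151758, 88117 to 90720, 12246 to 14030, 199485 to 201145 and 85153 to 86744. Of the total gaps only the first held positions of the other lists, with 1 in each H2A.Z list.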

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

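The tests of close pairs in this part were fixed before their results were seen. The differences between list types were read from the finished tables and were not tested, since each rests on 1 library per group.

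For 4 measures the difference between the H2A.Z and total libraries went one way in the paired-end lists and the other way in the single-end lists. The median distance between neighbouring centres was 1.905 bp longer in H2A.Z by paired-end data and differed by -0.9778 bp by single-end data. The share of neighbours under 100 bp apart differed by -3.659 percentage points (paired-end) and by 0.7529 (single-end), H2A.Z minus total. The share of neighbours 140 to 200 bp apart was higher in H2A.Z by 1 percentage point with paired-end data and differed by -6.128 with single-end data. The median distance between forward and reverse peaks differed by -1.205 bp and by 0.1966 bp. In each measure the 95% intervals of the libraries, which cover counting error only, overlapped in at least 1 list type, so these opposite signs need not be a difference. They overlapped for the median spacing in paired-end (135 to 142 bp in H2A.Z, 132 to 140 bp in total) and single-end lists (159 to 162 and 161 to 163 bp). For the share under 100 bp they overlapped in single-end lists (8.53 to 11.2% and 7.83 to 10.4%). In paired-end lists they only touched (25.1 to 28.8% and 28.7 to 32.5%), which does not exclude a difference there. For the share of 140 to 200 bp they overlapped in paired-end lists (40.1 to 44.2% and 39.2 to 43.2%) but not in single-end lists. For the peak distance they overlapped in single-end lists (127.6 to 128.6 and 127.3 to 128.5 bp) but not in paired-end lists.

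The paired-end lists held many centres less than 100 bp apart, which numbered 719 in the total and 609 in the H2A.Z paired-end list. Some of these entries have a fractional identifier, whose meaning the files do not give, and a second round of model fitting could produce them. At least 1 fractional identifier was present in 58.7% of the total close pairs, against 38.7% of the other neighbouring pairs, and in 49.9% against 33.4% in H2A.Z. Pairs with only whole identifiers made up 41.3% (37.8 to 44.9%) and 50.1% (46.1 to 54.0%), so fractional entries do not account for all close pairs, and their part in the rest stays open. The other explanation, alternative positions taken in different cells, requires close pairs to recur at the same places. Of the H2A.Z close pairs 41.7% (37.9 to 45.7%) had their midpoint within 50 bp of that of a total close pair. Circular shifts gave 18.3% (central 95% of shifts reaching 22.0%). The shifts also break the shared placement of the 2 maps, in which 69.4% of H2A.Z positions lay within 20 bp of a total one. Shared placement alone can raise the share above the shifts, so the comparison cannot show that close pairs themselves recur. The share would follow from alternative positions, but also from a model that splits similar read profiles the same way in both libraries. Centres less than 10 bp apart numbered 29 in the total and 21 in the H2A.Z paired-end list, against 0 and 1 in the single-end lists. Whether these closest pairs are alternative positions or repeated calls of 1 position was not tested.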

How the results depend on the processing

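Of 86 alternatives to 28 results, 38 stayed within the interval of the reported value (or within 1.5 times a count). For the number of positions called, the upper 75% of scores stays within this limit by construction. The other 48 alternatives to the 28 results moved outside. Most of these results are levels, with no direction to reverse; of the differences between libraries, the 4 given above changed sign in single-end lists, and removal of positions under 100 bp from a higher-scoring one turned the spacing in paired-end (163.8 bp in H2A.Z, 164.2 bp in total) and in single-end lists (167.0 and 166.7 bp), so that the list types still differed in sign. The paired-end spacing difference also turned in the upper 75% of scores and for whole identifiers, so H2A.Z was the longer only in the paired-end list as deposited and in single-end lists after that removal. The removal also turned the paired-end share of 140 to 200 bp (60.8 and 63.3%). With a match distance of 10, 50 and 73 bp the share of single-end positions matched was 64.9, 97.9 and 98.9% in total chromatin and 64.5, 98.1 and 99.0% in H2A.Z, and that of H2A.Z positions matched to total ones was 49.4, 92.4 and 97.2%; a wider distance raises a share by construction, and chance reached 85.1% at 73 bp for the last. In the upper 75% and 50% of scores the shares were 84.7 and 88.7% (total), 83.4 and 89.0% (H2A.Z), and 66.7 and 63.8% (H2A.Z to total). The H2A.Z to total share was 82.4% in single-end lists, and, with settings chosen after seeing the data, 95.1% for the top 10% of H2A.Z positions and 58.7% for entries with whole identifiers. Uniformly random positions gave chance levels of 25.7, 24.9 and 25.7%. The median spacing of total paired-end positions was 159.7 bp in the upper 75% of scores, 164 bp after removal of positions under 100 bp from a higher-scoring one, 162 bp in single-end lists and 154.7 bp for whole identifiers (added later); in H2A.Z these were 158.4, 164, 161 and 154.3 bp. In the upper 50% of scores and in single-end lists, the fitted peak distance was 127 and 128 bp in total, and in H2A.Z it moved only in single-end lists, to 128 bp. The forward SD was 24.0 and 30.0 bp in total and 25.2 and 30.8 bp in H2A.Z, and the standard error of the centre was 1.45 and 2.23 bp in total and 1.82 and 2.78 bp in H2A.Z. Rank correlations between list types rose to 0.938 (total) and 0.969 (H2A.Z) at 10 bp. In the top 10% of each list, a setting added later, 59.3% of the positions in both ends were from H2A.Z, 16 against 11 from total chromatin. These counts are small and the ends went opposite ways. The first 20 kb had 2 H2A.Z and 7 total positions, and the last 20 kb had 14 and 4. Of H2A.Z positions in the first 30 kb 4.41% were in the top 10%, and in the first 10 kb 0%, against 1.33% in the first 20 kb. The count of windows apart from the whole was 0 in every setting run, a count that the near-equal numbers of positions leave little room to change, and the gap shares stayed within their intervals. The causes of these changes were not tested, except where the setting fixes them.

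No paired analysis was possible because each group has 1 library and the labels carry no replicate numbers; for the same reason no replicate was left out. Comparisons at gene starts and over gene lists were not run, as positions were not assigned to genes. Read depth is unknown from the lists, so its effect on the number of positions and on the standard errors was not tested.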

Other observations

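All comparisons of strong positions in this part, and the test of long empty stretches, were chosen after the position lists had been seen; the tests of neighbour distances and pairs were written down before their own results.

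Strong H2A.Z positions often lay in spaced pairs. Of the 226 H2A.Z positions in the top 10% by score, 62.8% had another such position 220 to 400 bp away, against a mean of 24.0% when the top scores were assigned at random to H2A.Z positions and at most 36.3% in 2000 such draws. In total chromatin the share was 42.1%, against 24.6% at random and at most 37.0%. At 100 to 220 bp, the distance of direct neighbours, 48.1% of the strong total positions had another strong one, against 20.3% at random and at most 33.2%. Of the strong H2A.Z positions 27.4% had one, against 19.2% at random, a value within the random draws, of which 27 of 2000 were as large and the highest reached 30.5%. At 400 to 1000 bp the share in H2A.Z was 61.9%, against 60.0% at random, with 682 of 2000 draws as large. In total chromatin it was 69.4%, against 61.7% at random, with 58 of 2000 draws as large. The random draws do not keep the unevenness of top scores along the chromosome. In single-end lists the shares at 220 to 400 bp were 60.8% in H2A.Z and 41.5% in total chromatin. Of the 5 highest-scoring H2A.Z positions, that at 46896 had its partner at 47187 and that at 185989 at 186325. That at 52671 had its partner at a lower coordinate, 52348, as did that at 246584, at 246252. Only the pair of the position at 289253 had no total centre more than 50 bp from both members between them in either total list.

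Strong H2A.Z positions lay beside wide distances between centres of the total map. The wider of the distances to either neighbour, measured in the total single-end list, had a median of 242 bp (interquartile range 182 to 271 bp) for the strong H2A.Z positions and 170 bp (158 to 184 bp) for the others, a difference of 71.5 bp (bootstrap interval 57.2 to 79.9 bp). Random choices of 10% of the positions reached at most 6.08 bp. Both treat positions as independent, but the members of a spaced pair can border the same wide distance. Of the 88 strong H2A.Z pairs 220 to 400 bp apart, 52 had no total single-end centre between them more than 50 bp from both. The interval and the random limit can therefore be too narrow, and the spaced pairs and wide distances are not separate observations. Only positions within 73 bp of a total single-end centre and distances up to 1000 bp were used, which kept 225 of 226 strong and 1910 of 2038 other H2A.Z positions. This distance was 220 bp or more for 60.4% of the strong H2A.Z positions (53.9 to 66.6%) and 9.32% of the others (8.10 to 10.7%). In total chromatin it was so for 34.5% of the strong positions (28.7 to 40.8%) and 12.7% of the others (11.3 to 14.2%). Without both limits, a setting added later, the shares were 60.6% and 12.4% in H2A.Z and 34.5% and 14.9% in total chromatin, and the differences in the median were 72.0 and 9.14 bp. A hypothesis is that H2A.Z is enriched in nucleosomes that border nucleosome-depleted DNA, as at promoters, where H2A.Z is known to occur; genes were not assigned here, so promoters themselves were not tested.

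A technical alternative is that any nucleosome beside a wide distance scores high, because it is well placed or easily cut out. The medians argue against this as the whole cause, since the same difference in total chromatin was 10.7 bp (6.37 to 18.2 bp), 0.149 of that in H2A.Z (0.0850 to 0.265), but the shares at 220 bp or more leave it open as a part. The ratio of medians makes the libraries look further apart than the upper quartiles do. The median of the strong positions was 242 bp in H2A.Z and 182 bp in total chromatin, and the upper quartile was 271 and 260 bp. With distances taken from the H2A.Z single-end list the differences were 79.1 and 13.1 bp, with single-end scores 77.2 and 23.5 bp, for the top 5% 89.7 and 11.7 bp, and for the top 20% 21.5 and 6.57 bp. Of these, 23.5 bp in total chromatin and 89.7 and 21.5 bp in H2A.Z lay outside the intervals given above, so the ratio depends on the setting. That the pairs are second-next neighbours in a regular array stays open for part of them: 36 of 88 H2A.Z pairs 220 to 400 bp apart, or 40.9% (30.5 to 51.9%), had a total single-end centre between them, more than 50 bp from both, against 74.1% of 58 such pairs in total chromatin (60.96 to 84.74%). The finding rests on 1 library of each kind and was not checked in a replicate.

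In 6 stretches the total paired-end list had no position for over 1 kb. All 6 were empty over the middle 80% of their length in each of the 4 lists, which would follow from stretches without usable reads, as from repeated sequence or sequence that this strain lacks, and as well from missing nucleosomes. The test does not favour either, and a genome sequence and the reads were not used here. The absence of strong H2A.Z positions from 80 to 90 kb belongs beside this: 3 of the 6 stretches, between 85153 and 90720, lie in or reach out of that window, which held 42 H2A.Z positions. It held 43 total positions, of which only 2 were in the top 10%. The first 20 kb hold 1 of the stretches, and the window from 0 to 10 kb, with 89 H2A.Z positions and 0 strong ones, holds none.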
